A study of Nicotiana with 12 samples.

How the data were processed

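Leaf RNA from 12 tobacco samples was measured, 3 biological replicates in each of 4 groups: WT and PSARK::IPT plants, each watered with 1000 mL per pot and day or stressed with 300 mL for 45 days. Per the labels' protocols, total RNA was extracted with Trizol and biotinylated cRNA was hybridised to the Affymetrix Tomato Genome Array. The deposited values are log2 values that the authors made with RMA, per the submitters' processing notes; RMA corrects background, normalises across arrays and combines the probes of a probe set. The version and options of RMA are not given in the sources used here. The log2 scale was read from the values, which lay between 1.28 and 13.84 on all 12 arrays. Scanner files and detection calls were not used here, so signal over background is unknown per probe set. For arrays, their number limits the precision.

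Of 10209 probe sets, the 108 control probe sets were left out and 10101 were tested, with no filter on dim ones. The probe annotation gave exactly 1 gene symbol to 909 probe sets, several to 0 and none to 9192. The 909 name 803 genes, of which 176 have a LOC symbol only, and 82 have several probe sets. The annotation is that of tomato genes and gives no titles, so gene functions in the text are background knowledge.

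The groups, comparisons, tests, gene lists, rule for named genes and first set of alternatives were chosen before the data were examined. A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 8 residual and 7.99 prior degrees of freedom. The comparisons were stressed against watered in WT and in IPT, IPT against WT when watered and under stress, and the difference of the stress effects (IPT minus WT). Errors are the moderated standard errors of limma, and tests are two-sided. A probe set passed at a Benjamini-Hochberg adjusted p under 0.05 over all probe sets of that comparison, and "rose", "fell", "higher" and "lower" are used of genes that passed. The 2 agreement correlations are across probe sets.

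Of 36 gene lists fixed by symbol patterns, 23 had at least 3 named genes and were tested, 20 of pathways and 3 of tissue markers. Each gene entered with its probe set of highest mean, against the 627 genes with a symbol other than LOC. The test was camera from limma with a preset correlation of 0.01 between genes, which compares a list with the other genes, adjusted over the 23 lists of a comparison. Beside it stand camera with an estimated correlation and fry, with statmod 1.5.0, which asks whether a list moves 1 way without comparing it with other genes. None of the camera calls held with an estimated correlation. In lists whose members went both ways the mean, the median and the direction of camera could differ in sign, as for carotenoid synthesis between stressed genotypes (mean 0.11, median -0.17). The pattern for the Calvin cycle matched only PRK1, PRK2 and PRK3 and that for aquaporins only SIP, Sip1, TIP and pip1, symbols that also name other kinds of gene, so neither list is read as that pathway.

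Named genes are, per comparison, the 8 largest rises and 8 largest falls among named probe sets that passed, 1 probe set per gene, filled by the smallest p where fewer passed, and the 2 members with the smallest p of each list tested. Further list members were named after their values were seen, to complete counts or lists. A gene named in 1 comparison was followed in the others.

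Alternatives were median-centring, quantile normalization, above-median brightness, 1 probe set per gene, array weights, an intensity trend with robust moderation, a minimum log2 change of 1, only the arrays of the groups compared, the replicate number as a block, all probe sets of each gene, and leaving out each array in turn. A covariate (the 3' minus 5' difference of the poly-A controls), all probe sets as background, and leaving out the Calvin cycle and aquaporin lists were added after the data were seen. The poly-A controls and the other control probe sets were compared by exact two-sided permutation tests.

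The steps were tested on simulated data of 10101 probe sets with 4 groups of 3. Each comparison was simulated once, with independent errors, no labelling bias and the same mean and spread in all groups. In each, 67, 67 and 66 probe sets were changed by log2 0.5, 1 and 2. Between the comparisons of 3 against 3 arrays the shares therefore differ only by the draw. In WT stress, 29.9% of changes of log2 0.5 were recovered, 92.5% of 1 and 100% of 2, and 1.99% of calls were false. In IPT stress the shares were 40.3%, 95.5% and 100%, with 7.10% false. They were 31.3%, 95.5% and 100% between watered genotypes, with 3.82% false, and 38.8%, 95.5% and 98.5% between stressed genotypes, with 5.49% false. For the difference of the stress effects they were 10.4%, 76.1% and 100%, with 3.13% false. With 627 simulated genes, the shifted list was found in all 5 comparisons, and 0 of the 22 other lists were called. That list was the cell wall list of 36 genes, shifted by 0.5 with independent errors. The lists called in the data had 3 to 6 genes, and recovery of lists so small was not tested.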

Results

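Leaf RNA of wild-type (WT) tobacco and of a transgenic tobacco line, called IPT here, was measured on a microarray made for tomato. The line carries IPT, the gene of isopentenyltransferase, an enzyme of cytokinin synthesis, behind the promoter of SARK, a senescence-associated receptor kinase. Plants of each genotype received either 1000 mL of water per pot and day (watered) or 300 mL (stressed) for 45 days. Each of the 4 groups had 3 biological replicates, 1 array each, so 12 arrays in all. Of 10101 probe sets tested, 909 had a gene symbol of a tomato gene and 9192 had none in the annotation used here. Tobacco RNA was read with tomato probes, so a probe set is compared with itself between groups and never with another probe set. The IPT gene itself was not among the named probe sets, so its level could not be used to check the labels.

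Array medians lay between 3.40 and 3.47 on the log2 scale, and replicate arrays correlated with r between 0.982 and 0.992 over all probe sets. The number of arrays limits the precision. The first principal component held 42.1% of the variance and parted WT from IPT arrays, and the second held 21.0% and placed the watered arrays of each genotype above its stressed ones. Stressed WT replicate 2 lay at -24.6 on the second component, against -9.86 and -8.96 for the other stressed WT arrays.

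The poly-A control transcripts, bacterial RNAs added to the samples before labelling, differed between the groups. Their mean log2 level was 10.06 ± 0.05 (SD, n = 3) in watered WT, 8.04 ± 0.41 in stressed WT, 8.32 ± 0.14 in watered IPT and 8.58 ± 0.09 in stressed IPT. The watered WT arrays lay between 10.02 and 10.11 and all other arrays between 7.57 and 8.67, and the labels give no batch. The log2 difference between their 3' and 5' probe sets, a measure of how far labelling reached along a transcript, was 2.24 ± 0.07 in watered WT and 4.36 ± 0.94 in stressed WT. It was 2.67 ± 0.45 in watered IPT and 3.42 ± 0.14 in stressed IPT. Each stress difference had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays can give. Within every group, arrays with a larger 3' minus 5' difference lay lower on the second principal component. In watered IPT, arrays with 2.21, 2.68 and 3.11 lay at 10.2, 5.10 and 0.723. Stressed WT replicate 2 had the largest difference, 5.43, against 3.93 and 3.70 in its group. The second component therefore cannot be read as water supply alone.

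**Figure D1:**
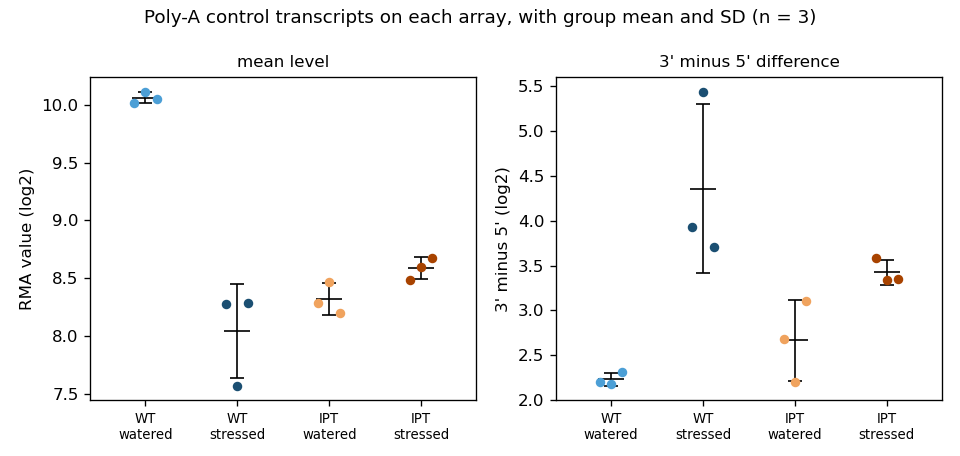
Poly-A control transcripts on each of the 12 arrays (points), with group mean and SD (n = 3). The left panel plots their mean RMA value (log2), 10.06 in watered WT and between 8.04 and 8.58 in the other groups, and the right panel plots 3' minus 5' (log2), with stressed WT at 4.36.

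What water stress did to WT leaves was the first comparison. TBG3, a beta-galactosidase, rose 9.24-fold (log2 change 3.21, SE 0.12, 3 arrays against 3, limma adjusted p = 7.18e-11). The bZIP transcription factor abz1 rose 2.57-fold (log2 1.36, SE 0.15), the fructokinase FRK2 2.48-fold (log2 1.31, SE 0.12) and GAL83, a subunit of the SnRK1 kinase complex, 1.96-fold (log2 0.97, SE 0.13). The carbonic anhydrase ca2 fell 6.16-fold (log2 change -2.62, SE 0.18, adjusted p = 1.03e-07), and a second of its 4 probe sets fell with it. Fad7, a plastid fatty acid desaturase, fell 2.58-fold (log2 -1.37, SE 0.12), and a probe set of XTH16, a xyloglucan-modifying enzyme, fell 4.14-fold (log2 -2.05, SE 0.17).

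BMY3 (log2 1.60, SE 0.31), PTOX, the plastid terminal oxidase (1.01, SE 0.19), LOC543605 (1.34) and LOC544312 (1.22) also rose. VPE5, a vacuolar processing enzyme (-1.45, SE 0.18), LOC544267 (-1.49), the endoglucanase Cel1 (adjusted p = 0.000356), the blue-light receptor CRY1A (-0.82) and MDHAR, monodehydroascorbate reductase (-1.25, SE 0.23), fell. For BMY3, VPE5 and CRY1A the other probe sets of the gene did not pass in that direction. With the 3' minus 5' difference of the poly-A controls as a covariate, the values of TBG3 (3.39), ca2 (-1.66), Fad7 (-1.07), abz1 (1.54) and GAL83 (1.31) still passed. Under that covariate FRK2 (1.08, adjusted p = 0.0531), VPE5 (-0.91), PTOX (0.71), BMY3 (0.52), CRY1A (-0.24), Cel1 (-0.74) and LOC544267 (-1.75) no longer passed, and MDHAR turned to 0.10. The covariate widened the standard errors of the probe sets called in WT by a median of 1.92 times.

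The light-harvesting gene CAB4, of a chlorophyll a/b-binding protein, fell in stressed WT leaves (-0.63, SE 0.10). The mean log2 change of the light-harvesting complex list was -0.40 (3 genes, camera adjusted p = 0.00386), with adjusted p = 0.196 with an estimated correlation. CAB5 (-0.30) and CAB6A (-0.28) did not pass, and 3 of 3 were lower adjusted over the list alone. The photosystem II list had a mean of -0.21 (4 genes, camera adjusted p = 0.0372, adjusted p = 0.196 with an estimated correlation), and this mean turned to 0.04 with quantile normalization. None of its 4 members passed, 0 higher and 0 lower, and 2 were lower adjusted over the list alone, PsbQ (-0.30) and PSBP (-0.30). The 3' minus 5' difference of the poly-A controls was 2.12 higher on the same arrays and their level -2.02 relative to watered WT. The 3' minus 5' difference of control probe sets for leaf transcripts was also higher, by 0.71 for GAPDH (pooled SD 0.231), 0.65 for EF1a (0.172) and 0.93 for actin (0.497), each with exact permutation p of 0.1, and by 0.11 for ubiquitin. With the poly-A difference as a covariate neither list passed, at means of -0.44 (adjusted p = 0.141) and -0.21 (0.462). The photosystem II list passed in 2 of the 6 fits that left out 1 WT array, with adjusted p between 0.0324 and 0.106.

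Other lists held members that passed in WT, and camera called none of these lists. Fry called the ethylene (adjusted p = 0.00138), heat-shock (0.00198), cell wall (0.00198) and dehydration-protective lists (0.0405). Of 36 cell wall genes, 7 rose, 2 fell and 27 did not pass, and 9 passed adjusted over the list alone. XTH16 is counted by its probe set of highest mean, which did not pass (-0.02), and not by those that fell (-2.05 and -0.46). Beside TBG3, TBG4 (0.64, SE 0.12) rose, and the endoglucanases Cel1 and CEL8 (-0.57) fell. Of 15 oxidative stress enzymes, 2 rose, the glutathione peroxidase GPXle-1 (0.62, SE 0.11) and the catalase cat1 (0.49, SE 0.11), and MDHAR fell; 5 passed adjusted over the list alone. Of 5 dehydration-protective genes, the dehydrin TAS14 (0.73) and ER5 (0.54) rose. Of 6 heat-shock genes, HSP21 (0.95, SE 0.15) and HSC80 (0.61, SE 0.12) rose. Of 29 ethylene genes, 3 rose, among them EIL3 (0.68) and ETR5 (0.72), 0 fell and 26 did not pass, with 5 passing adjusted over the list alone. Of 18 sucrose and starch genes, FRK2 and sus3 (0.49) rose and AGPL3 (-0.52) fell. Without 1 of the arrays ER5 (adjusted p up to 0.193), ETR5 (0.108), AGPL3 (0.132) and CRY1A (0.0859) no longer passed. With the poly-A covariate CAB4 (-0.66), HSP21 (1.21), AGPL3 (-0.56) and GPXle-1 (0.63) did not pass either, at folds no smaller than without it. HSC80 (0.52), EIL3 (0.53), ETR5 (0.36), TAS14 (0.28) and ER5 (0.13) did not pass at smaller folds.

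In all, 1142 of the 10101 probe sets passed in WT, 569 higher and 573 lower, and 2528 had an unadjusted p under 0.05. Of those that changed at least 2-fold, 34 were higher and 138 lower. Without stressed WT replicate 2 the count was 748, with 87 falls and 34 rises of at least 2-fold, with only the WT arrays in the fit it was 694, and with the poly-A covariate 59.

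**Figure D2:**
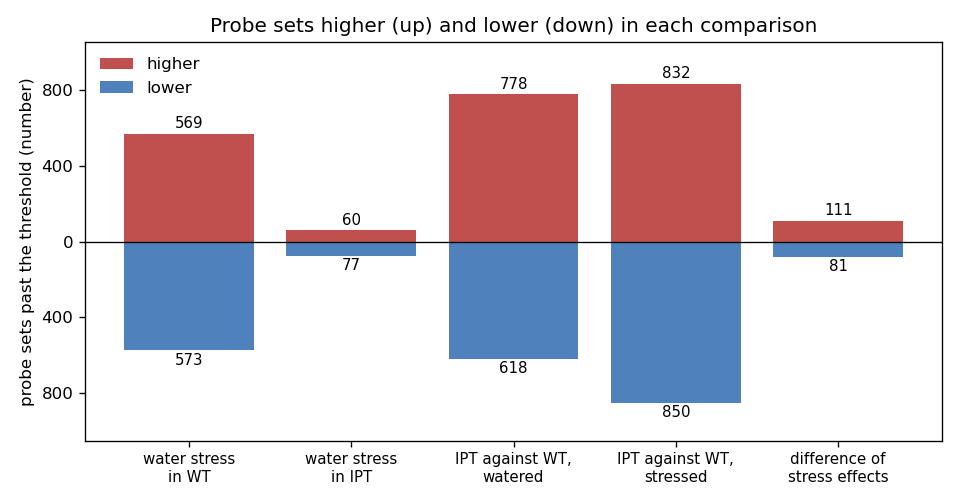
Number of probe sets higher (red bars, upward) and lower (blue bars, downward) past the limma threshold in each of the 5 comparisons, out of 10101 tested. Water stress gave 569 higher and 573 lower in WT, against 60 and 77 in IPT.

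The same stress in IPT leaves was the next comparison. GluB, a beta-1,3-glucanase, rose 2.15-fold (log2 1.10, SE 0.17, n = 3 arrays per group, limma adjusted p = 0.00171), and PR-5, a thaumatin-like defence protein, rose 1.92-fold (log2 0.94, SE 0.22, adjusted p = 0.0424). The endoglucanase CEL8 (0.56, SE 0.12), the alpha-galactosidase AGAL (0.59, SE 0.12), the malic enzyme ME2 (0.54, SE 0.11), LOC544153 (0.67), LOC543515 (0.65) and LOC543709 (0.62) rose as well. AGAL lay between 2.29 and 3.06 on all arrays, below the array medians. VPE5 fell 2.26-fold (-1.18, SE 0.18, adjusted p = 0.00171), CRY1A fell 2.16-fold (-1.11, SE 0.21) and a probe set of XTH16 fell 1.69-fold (-0.76, SE 0.17). The other probe sets of VPE5 (0.10 and 0.14) and CRY1A (0.13) did not pass. LOC543916 (-0.65, adjusted p = 0.0569), LOC543955 (-0.52), PRO1 (-0.52), LOC544064 (-0.36) and the transcription factor DREB3 (-0.33, adjusted p = 0.171) came next and did not pass.

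TBG3 (0.04, SE 0.12), ca2 (-0.24, SE 0.18), Fad7 (0.43, SE 0.12) and FRK2 (-0.16, SE 0.12), which changed in WT, did not pass in IPT. None of the 4 photosystem II genes (mean 0.01), the 3 light-harvesting genes (0.09), the 5 dehydration-protective genes (-0.00) or the 6 heat-shock genes (0.12) passed. Of 13 pathogenesis-related genes 1 rose, PR-5, and of 36 cell wall genes 1 rose, CEL8, with 4 passing adjusted over the list alone. XTH16 is counted there by its probe set of highest mean (0.25, not passing), not by the one that fell (-0.76). With camera, 0 of 23 lists passed, 4 had an unadjusted p under 0.05, and fry called 1, the markers of dividing and meristem cells (mean 0.19, fry adjusted p = 0.0234, camera adjusted p = 0.175). Of these 11 genes, 9 had values above 0 and 0 passed.

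In IPT, 137 probe sets passed, 60 higher and 77 lower, with 21 and 24 of them changed at least 2-fold, and 1437 had an unadjusted p under 0.05. The count was 54 without watered IPT replicate 2, 62 without watered replicate 1, 81 without stressed replicate 1 or 2, and 64 with the poly-A covariate. Of the 11 named probe sets that passed, only those of GluB and VPE5 passed in every fit that left out 1 array, and with the poly-A covariate those of GluB, VPE5 and ME2 passed and the other 8 did not, among them PR-5 (1.10), CRY1A (-0.90), AGAL (0.54), CEL8 (0.47) and XTH16 (-0.53). On the stressed IPT arrays the 3' minus 5' difference was 0.76 higher for the poly-A controls, 0.56 for GAPDH and 0.32 for ubiquitin, each with exact permutation p of 0.1, and 0.81 for actin and 0.17 for EF1a, with p of 0.3 and 0.2.

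How far the transgene's line differed from WT without stress was asked of the watered plants. GA20OX1, a gibberellin 20-oxidase, was 9.40-fold higher in IPT (log2 3.23, SE 0.29, n = 3 arrays per group, limma adjusted p = 7.76e-07). On the watered WT arrays it stood at 1.95, 2.65 and 3.07, below the array medians, so background may enter this fold. VDE, violaxanthin de-epoxidase of the xanthophyll cycle, was 7.09-fold higher (2.83, SE 0.17), with its other probe set at 1.22. FRK2 was 6.32-fold higher (2.66, SE 0.12). XTH16 was 4.65-fold higher (2.22, SE 0.17), with its other probe sets also higher, at 1.35 and 0.94. SPM1 was 6.25-fold lower (-2.64, SE 0.12, adjusted p = 2.08e-10), TAS14 6.01-fold lower (-2.59, SE 0.15), and CrtR-b1, a beta-carotene hydroxylase, 4.05-fold lower (-2.02, SE 0.13). The tubulin TUB (1.59), LOC543968 (1.44), the protease SBT1 (1.44) and LOC543561 (1.39) were higher, and the malic enzyme ME1 (-1.92), FDH, formate dehydrogenase (-1.83), CIP1 (-1.59) and CIP2b (-1.56) were lower. The other CIP1 probe set (-0.36) did not pass.

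Most of the genes of protection against heat and dehydration were lower in watered IPT leaves. Of 6 heat-shock genes, 4 were lower, 0 higher and 2 did not pass, and 4 were lower adjusted over the list alone (mean -0.59, camera adjusted p = 0.0201, adjusted p = 0.237 with an estimated correlation). They were the small heat-shock gene HSP17-6 (-1.93, SE 0.19), HSC80 (-0.59), Hsp90-1 (-0.53) and HSP21 (-0.48). Of 5 dehydration-protective genes, 3 were lower, 0 higher and 2 did not pass, with 3 lower adjusted over the list alone (mean -0.86, adjusted p = 0.0201, adjusted p = 0.264 with an estimated correlation). They were TAS14 and the lipid transfer protein genes TSW12 (-1.31, SE 0.11) and ltpg1 (-0.70, SE 0.18). The mean level of the poly-A controls was 1.74 lower on the watered IPT arrays than on the watered WT arrays, and their 3' minus 5' difference was 0.43 higher. That of ubiquitin was -0.58 in IPT relative to WT (pooled SD 0.149, exact permutation p = 0.1), of EF1a -0.19 (0.187), of GAPDH 0.28 (0.236) and of actin 0.04 (0.190). With the poly-A difference as a covariate both lists passed (adjusted p = 0.0297 each).

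Of 9 carotenoid genes, 3 were higher and 3 lower, and the list did not pass (adjusted p = 0.863). VDE, CRTL-E-1 (0.63) and LCY1 (0.48) were higher, and CrtR-b1, the phytoene synthases PSY2 (-0.69) and Psy1 (-0.49) lower. The other Psy1 probe sets (0.28 and 0.12) did not pass. Of 15 oxidative stress enzymes, 4 were lower, 0 higher and 11 did not pass, among them the catalase CAT2 (-0.90, SE 0.11) and the superoxide dismutase SODCC.1 (-0.75, SE 0.10), with 5 passing adjusted over the list alone (adjusted p of the list 0.0628). Of 4 photosystem II genes, 3 were higher, PSBP (0.55), PSBO (0.46) and PsbQ (0.41), and the list did not pass (adjusted p = 0.0628). Of 18 sucrose and starch genes, FRK2 and AGPL3 (0.99, SE 0.15) were higher and SPS, sucrose-phosphate synthase (-1.08, SE 0.21), and sus3 (-0.52) lower. Of 3 nitrogen genes 1 was higher, GS2, the plastid glutamine synthetase (0.59, SE 0.11), and of 29 ethylene genes 3 were higher, among them the ACC oxidases ACO6 (1.03) and ACO4 (0.76). The other ACO6 probe sets (0.35 and 0.08) did not pass. ACO4 reached adjusted p = 0.0519 without watered WT replicate 1.

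Between the watered genotypes 1396 probe sets passed, 778 higher and 618 lower in IPT, with 125 and 145 of them at least 2-fold, and 2555 had an unadjusted p under 0.05. With each array centred on its median, the split was 606 higher and 743 lower.

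**Figure D3:**
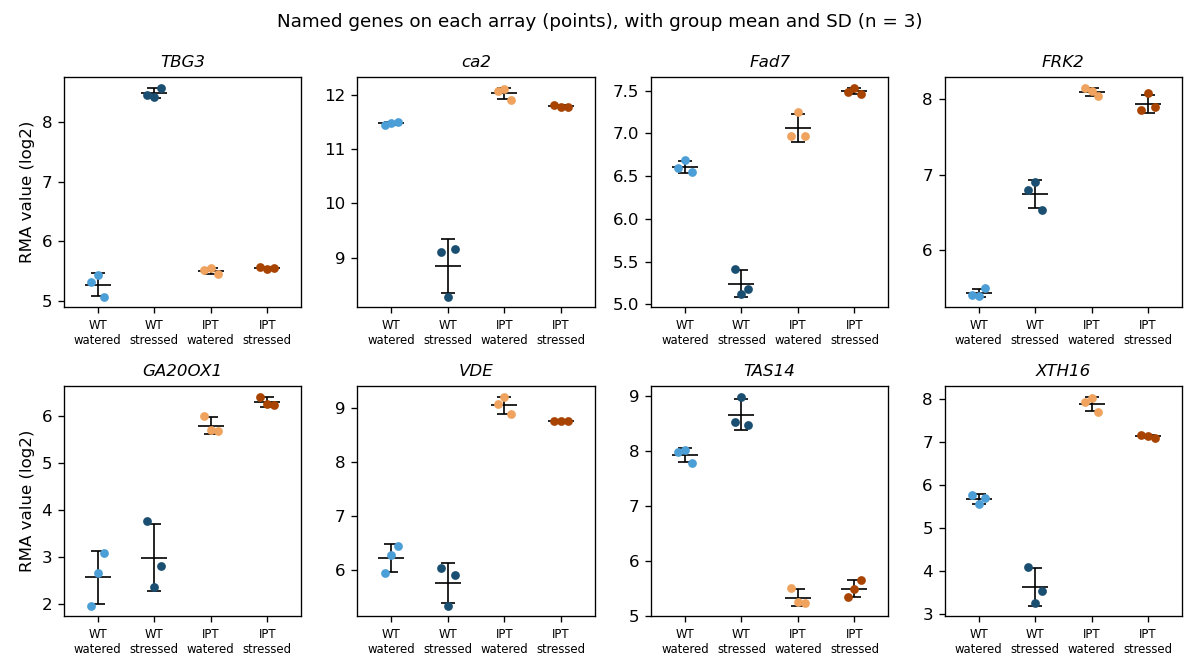
RMA values (log2) of 8 named genes on each of the 12 arrays (points), with group mean and SD (n = 3); each panel has its own vertical range. TBG3 stands at 8.48 in stressed WT and between 5.27 and 5.54 in the other groups, and GA20OX1 and VDE are higher on all 6 IPT arrays than on all 6 WT arrays.

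The genotypes were then compared under stress. A probe set of XTH16 was 11.4-fold higher in IPT (log2 3.51, SE 0.17, n = 3 arrays per group, limma adjusted p = 4.82e-10). GA20OX1 was 9.92-fold higher (3.31, SE 0.29), ca2 8.03-fold (3.01, SE 0.25), VDE 7.98-fold (3.00, SE 0.17) and Fad7 4.78-fold (2.26, SE 0.12). Other probe sets of these genes differed less: XTH16 at 1.41 and 1.21, VDE at 0.66, and ca2 at 2.94, 0.86 and 0.24, the last not passing. GA20OX1 stood at 3.77, 2.36 and 2.81 on the stressed WT arrays, around the array medians, so background may enter its fold here too. TAS14 was 8.95-fold lower (-3.16, SE 0.15, adjusted p = 2.39e-10), TBG3 7.66-fold lower (-2.94, SE 0.12), BMY3 6.17-fold lower (-2.63, SE 0.31) and ME1 5.51-fold lower (-2.46, SE 0.10). The other BMY3 probe sets stood at -0.58 and at -0.51, the latter not passing. The lipid transfer protein gene LE16 (-2.43), CrtR-b1 (-2.26), SPM1 (-2.09) and LOC543605 (-2.56) were lower, and TUB (SE 0.12, adjusted p = 3.24e-09), LOC543968 (1.72) and HPL, a hydroperoxide lyase (1.55), higher.

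All light-harvesting genes and all photosystem II genes but PSBR were higher in stressed IPT than in stressed WT leaves. Of 4 photosystem II genes, 3 were higher, PSBP (0.89, SE 0.11), PsbQ (0.77, SE 0.10) and PSBO (0.61), and PSBR (0.05) did not pass; 3 were higher adjusted over the list alone. The mean was 0.58 (camera adjusted p = 0.0155, adjusted p = 0.162 with an estimated correlation), and with quantile normalization it was 0.36 and did not pass (adjusted p = 0.216). All 3 light-harvesting genes were higher, CAB4 (0.65), CAB6A (0.48) and CAB5 (0.35), with 3 adjusted over the list alone (mean 0.49, adjusted p = 0.0399, adjusted p = 0.223 with an estimated correlation). This list did not pass with quantile normalization (0.45, adjusted p = 0.0832) or without any 1 of the stressed WT arrays or stressed IPT replicate 1 (adjusted p up to 0.071). The 3' minus 5' difference of the poly-A controls was -0.93 in IPT relative to WT on these arrays. That of EF1a was -0.67 (pooled SD 0.110) and that of ubiquitin -0.37 (0.150), and the rRNA probe sets stood at -1.98 (1.10), each with exact permutation p of 0.1. With the poly-A difference as a covariate the photosystem II list passed (0.58, adjusted p = 0.0236) and the light-harvesting list did not (0.51, 0.0725).

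Most dehydration and heat-shock genes were lower in stressed IPT as well. Of 5 dehydration-protective genes, 4 were lower, TAS14, TSW12 (-1.40), ltpg1 (-0.57) and ER5 (-0.55), and 4 adjusted over the list alone (mean -1.16, adjusted p = 0.00851, adjusted p = 0.211 with an estimated correlation). Of 6 heat-shock genes, 4 were lower, HSP17-6 (-1.37), HSP21 (-1.32), HSC80 (-1.10) and Hsp90-1 (-0.45), and 4 adjusted over the list alone (mean -0.71, adjusted p = 0.0182, adjusted p = 0.162 with an estimated correlation). With the poly-A covariate both lists passed (adjusted p = 0.0231 each). The mean poly-A level was 0.54 higher on the stressed IPT arrays.

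Of 15 oxidative stress enzymes, 4 were lower, among them CAT2 (-0.99) and SODCC.1 (-0.89), and 0 higher, with 5 passing adjusted over the list alone and no call for the list (adjusted p = 0.138). Of 36 cell wall genes, 9 were higher, among them CEL8 (1.16), and 5 lower, with 14 passing adjusted over the list alone. Of 14 jasmonate genes, 3 were higher, among them HPL and AOC (0.51), and 1 lower, LAPA2 (-0.41). The cyclin gene CYCD3 was higher (1.11, SE 0.17), 1 of 11 markers of dividing cells, as it was when watered (0.66, SE 0.17). Of these markers 9 had values above 0 under stress, and fry called the list (mean 0.20, adjusted p = 0.00992) while camera did not (0.444). Of 12 stress transcription factors, AREB1 (-0.57) and WRKY2 (-0.59) were lower and 10 did not pass. With the poly-A covariate CAB6A (0.45, adjusted p = 0.0654), AOC (0.51, 0.0849), AREB1 (-0.47, 0.107) and WRKY2 (-0.41, 0.162) did not pass, and without 1 array AOC and WRKY2 reached adjusted p of 0.0974 and 0.0566. CYCD3 between watered plants reached 0.0804 without watered WT replicate 3.

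Under stress 1682 probe sets passed, 832 higher and 850 lower in IPT, with 192 and 157 of them at least 2-fold, and 2768 had an unadjusted p under 0.05. Of the 4 lists, 0 passed when the test was run on the probe sets of above-median brightness, and 2 passed without stressed WT replicate 3, where the heat-shock list reached adjusted p = 0.0508.

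**Figure D4:**
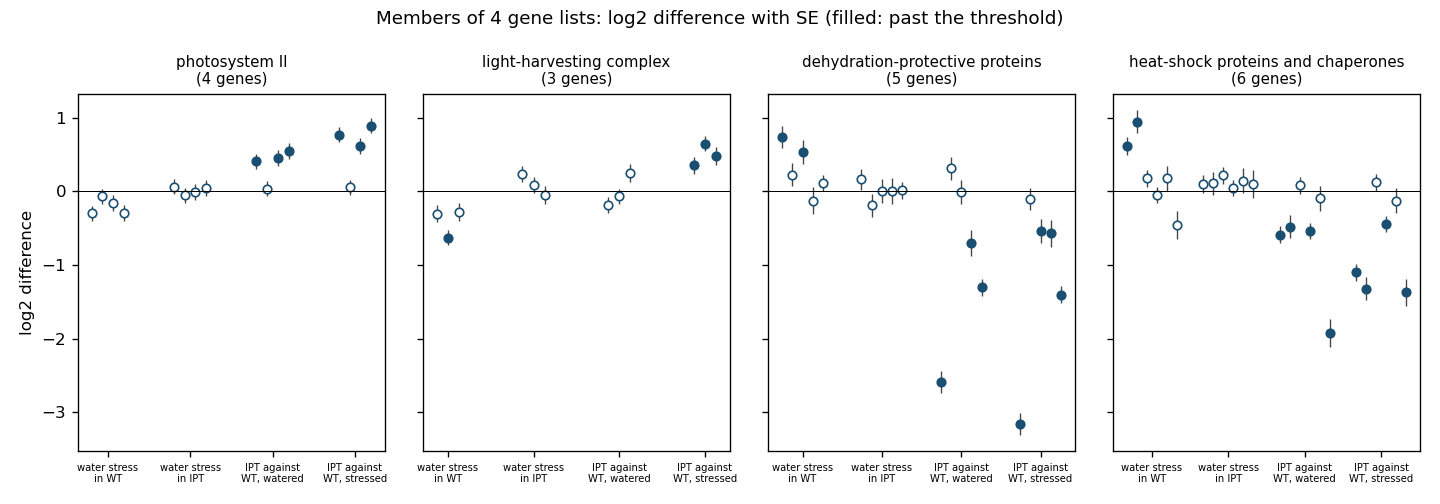
Log2 difference with SE (bars) for each member of 4 gene lists, in the stress comparisons and the genotype comparisons (3 arrays per group); filled circles passed the limma threshold. TAS14 lies lowest, at -2.59 between watered and -3.16 between stressed genotypes, and all 3 light-harvesting genes are filled between stressed genotypes.

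Whether the genotypes responded differently to stress was tested on the difference of their stress effects. TBG3 had a stress effect 3.17 lower on the log2 scale in IPT than in WT (-3.17, SE 0.17, n = 3 arrays in each of 4 groups, limma adjusted p = 1.92e-08), abz1 -1.53 (SE 0.22) and FRK2 -1.46 (SE 0.17). For ca2 the effect was higher in IPT by 2.38 (SE 0.25, adjusted p = 4.16e-05), for Fad7 by 1.80 (SE 0.17), for a probe set of XTH16 by 1.29 (SE 0.24) and for CEL8 by 1.12 (SE 0.17). CEL8 fell in WT and rose in IPT. GluB (1.08, SE 0.24, adjusted p = 0.024), PTI4, an ERF transcription factor (1.04, SE 0.23), LOC544153 (1.24) and LOC778315 (0.80) had higher effects in IPT. LOC543605 (-1.23), LOC544312 (-1.14), LOC543955 (-0.89), DDTFR18 (-0.88) and LOC543802 (-0.87) had lower ones. The other LOC543955 probe set (-0.04) did not pass. With the poly-A covariate GluB (1.23), LOC778315 (0.89), PTI4 (0.95), XTH16 (0.88) and LOC543955 (-0.65) did not pass (adjusted p between 0.0662 and 0.347). All of these but XTH16 also lost the call without at least 1 array. The covariate widened the standard errors of the called probe sets by a median of 1.23 times.

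Among 15 oxidative stress enzymes 1 differed, GPXle-1 (-0.74, SE 0.15), with 2 adjusted over the list alone, and among 14 jasmonate genes 1, LAPA2 (-0.71, SE 0.17), also with 2. With the poly-A covariate GPXle-1 (-0.75, adjusted p = 0.0772), LAPA2 (-0.73, 0.163) and CAB4 (0.73, 0.0706) did not pass, at folds no smaller than without it. LAPA2 also lost the call in 10 of the 12 fits that left out 1 array (adjusted p up to 0.124), and GPXle-1 and CAB4 in 0. Of 3 light-harvesting genes, CAB4 had a higher effect in IPT (0.71, SE 0.14, adjusted p = 0.0134), CAB5 (0.54) and CAB6A (0.23) did not pass, and 2 passed adjusted over the list alone. The mean of this list was 0.49 (camera adjusted p = 0.0129, adjusted p = 0.308 with an estimated correlation), and it did not pass with quantile normalization (0.44, adjusted p = 0.055) or with the poly-A covariate (0.52, adjusted p = 0.0515). The photosystem II genes (mean 0.22, 0 of 4 passing, adjusted p = 0.331), the heat-shock genes (mean -0.12, 0 of 6, with 2 adjusted over the list alone) and the dehydration-protective genes (mean -0.30, 0 of 5) did not differ past the threshold.

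In all, 192 probe sets had stress effects that differed, 111 higher and 81 lower in IPT, with 76 and 32 of these differences at least 2-fold, and 1432 had an unadjusted p under 0.05. Of the 111, 93 fell in WT and 27 rose in IPT, and of the 81, 74 rose in WT. The count was 120 with the poly-A covariate, 300 among probe sets of above-median brightness alone, and 332 with an intensity trend in the variance.

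**Figure D5:**
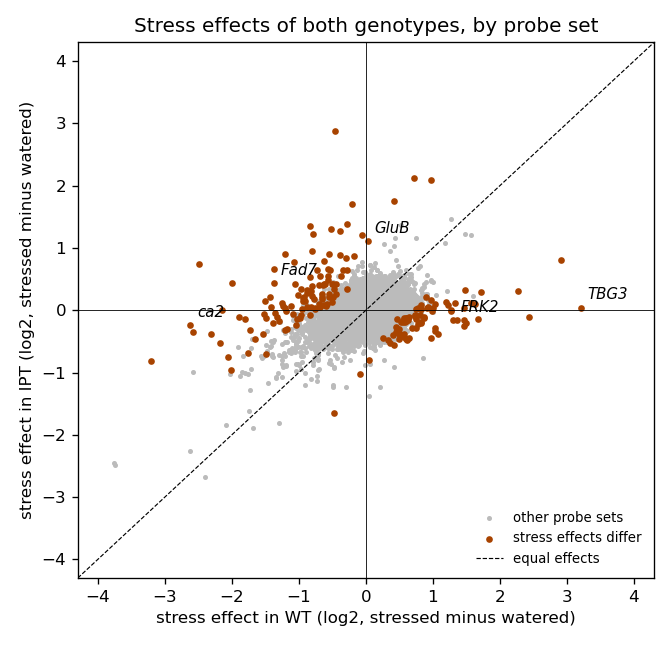
Stress effect (log2, stressed minus watered) of each of the 10101 probe sets in WT (horizontal axis) and IPT (vertical axis); coloured points are the 192 whose effects differed by limma, and the dashed line marks equal effects. TBG3 lies at 3.21 in WT and 0.04 in IPT, and ca2 at -2.62 and -0.24.

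Across all probe sets the stress effects of WT and IPT correlated with Pearson's r of 0.369 and Spearman's rho of 0.258; probe sets are not independent replicates. The 2 effects share no arrays. Of the probe sets past the threshold, 17 rose in both genotypes, where independent lists would share 3.38, and 52 fell in both, against 4.37. A probe set each of VPE5, CRY1A and XTH16 fell in both, and 11 probe sets moved in opposite directions, CEL8 and LOC544153 among those named. With the poly-A covariate those of VPE5 and CRY1A did not pass in WT, nor those of CRY1A and XTH16 in IPT. The 3' minus 5' difference of the poly-A controls was higher under stress in both genotypes (2.12 in WT, 0.76 in IPT). A shared response therefore cannot be told apart here from a labelling bias shared by both. The genotype effects under both water supplies correlated with r = 0.658. IPT exceeded WT under both for 436 probe sets (64.1 for independent lists), among them GA20OX1, VDE, FRK2 and XTH16. It lay below WT under both for 341 (52.0 for independent lists), among them TAS14, SPM1, CrtR-b1 and ME1, and 29 had opposite directions.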

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

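The test of the spread between arrays, the hybridisation test and the counts of other splits for probe sets were chosen after the result was seen, and the poly-A covariate was added after the data were seen.

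The stress effects of IPT and WT differed by a test of the difference for the genes with the 8 largest differences in each direction, among the 19 probe sets that the naming rule gave and that passed (log2, IPT minus WT). They were higher in IPT for ca2 (2.38), Fad7 (1.80), XTH16 (1.29), LOC544153 (1.24), CEL8 (1.12), GluB (1.08), PTI4 (1.04) and LOC778315 (0.80). Lower effects in IPT were found for TBG3 (-3.17), abz1 (-1.53), FRK2 (-1.46), LOC543605 (-1.23), LOC544312 (-1.14), LOC543955 (-0.89), DDTFR18 (-0.88) and LOC543802 (-0.87). The light-harvesting list differed by 0.49 (adjusted p = 0.0129, adjusted p = 0.308 with an estimated correlation), and it did not pass with quantile normalization (0.44, 0.055) or the poly-A covariate (0.52, 0.0515). Of 100 drawn splits of the arrays within genotypes, 2 gave as many probe sets as the real 192, the real one included (highest other 201), and 12 gave as many lists as the real 1 (highest other 2). Relabelling removes the stress effects themselves, so these splits do not test whether equal effects could give such counts. The 8 other splits that kept the grouping of the WT arrays gave between 91 and 201 probe sets.

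Signals outside the main measurement came from the poly-A controls. Their 3' minus 5' difference was 2.12 higher in stressed than in watered WT and 0.76 higher in stressed than in watered IPT, and their mean level was 0.54 higher in stressed IPT than in stressed WT. The larger level differences were -2.02 for WT stress and -1.74 between watered genotypes, against 0.27 for IPT stress, since the watered WT arrays (10.02 to 10.11) stood apart from all others (7.57 to 8.67). The labels give no batch, so a separate handling of the watered WT arrays cannot be told apart from their group, and it would enter WT stress, the watered genotypes and the difference of the stress effects.

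Many probe sets, 1396, differed between the watered genotypes. Unequal hybridisation stays open: the spike-in difference was -0.272 when watered (pooled SD 0.142), and 0.0889 under stress (SD 0.109), inside its spread. In IPT 436 probe sets were higher and 341 lower under both water supplies, against 64.1 and 52.0 for independent lists, and 29 had opposite directions. This does not decide it, since unequal hybridisation at both water supplies would also keep the direction, and the spike-ins under stress cannot exclude that. For RNA quality, 2 of 4 control transcripts differed by over 1 SD in 1 direction where the prediction needed 3. They were ubiquitin (-0.58, SD 0.149) and EF1a (-0.19, SD 0.187), while GAPDH moved the other way (0.28, SD 0.236). The prediction was not met, but RNA quality stays open, since ubiquitin lay far outside its spread (exact permutation p = 0.1). Bias toward 3' ends, as far as the poly-A controls measure it, was argued against because the effects kept a median ratio of 0.988 with the covariate. The poly-A difference was 0.43 between these groups and ubiquitin moved the other way, so bias that the poly-A controls do not follow was not tested. Sequence differences under single probe sets stay open: probe sets of a gene correlated by 0.167 more for the genotype effect than for the stress effect, with an interval from -0.305 to 0.855 over 82 genes. The poly-A level stood 1.74 lower in IPT when watered, and the genotype, which the design names, also stays open.

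Fewer probe sets passed the stress test in IPT (137) than in WT (1142). The median SD was lower in IPT (difference -0.0178), but this decides nothing about a larger spread between IPT arrays. The fit shared 1 spread per probe set, so both stress tests had the same median standard error, 0.143. As a cause, 1 atypical stressed WT array was argued against (748 at the lowest, against at most 125 in IPT). For probe sets chosen in WT, effects of equal size that missed the threshold were argued against (mean ratio 0.330 on held-out arrays). Probe sets chosen in IPT were not measured this way. The held-out WT arrays carried the 3' minus 5' difference of their group, so the ratio does not part a weaker response from labelling bias. The bias of the labelling toward 3' ends stays open: with its covariate the counts were 59 in WT and 64 in IPT, which meets what was written for it as the cause. That alone was not taken as its mark, by a rule added after this value was seen. The reason was that the covariate also widened the standard errors of the probe sets called in WT by a median of 1.92 times. With the covariate the mean signed effect of the probe sets called in WT went from 0.726 to 0.428 in WT and from 0.20 to 0.0936 in IPT, and a weaker response of the IPT genotype and a separate handling of the watered WT arrays, which enter only the WT count, also stay open.

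Falls of at least 2-fold outnumbered such rises in WT, 138 against 34. A single stressed WT array was argued against, since falls stayed at least 2.56 times rises without any 1 of them (87 and 34 without replicate 2). Bias toward 3' ends may account for part of it: with the covariate the falls kept a median ratio of 0.348 (0.253 to 0.396 without 1 array) and the rises 0.952. A biological excess of falls was not tested apart from it.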

How the results depend on the processing

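The poly-A covariate, all probe sets as background and the removal of the Calvin cycle and aquaporin lists were chosen after the data were seen; the cause was not tested except where stated. Of 4836 values of named genes under alternatives, 4509 kept direction and side of the threshold, 257 lost and 68 gained the call, and 2 reversed, both with the covariate in WT: MDHAR (0.10) and RPS25 (-0.021). Counts of probe sets are given in the order WT stress, IPT stress, watered genotypes, stressed genotypes, difference. A minimum log2 change of 1 gave 172, 45, 270, 349 and 108, by its construction. The covariate gave 59, 64 and 120 for WT, IPT and difference. There it widened the standard errors of the called probe sets by medians of 1.92, 1.12 and 1.23 times. Only the groups compared gave 694 in WT, with fewer arrays in the fit. An intensity trend gave 228 in IPT and 332 for the difference, array weights 254 in IPT, and above-median brightness 300 for the difference, with fewer probe sets tested.

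Shifted lists were 0 with an estimated correlation in WT, in both genotype comparisons and for the difference. With fry they were 9, 1, 9, 9 and 3. Quantile normalization gave 1 in WT, where the photosystem II mean turned to 0.039, 2 between stressed genotypes and 0 for the difference. In WT all probe sets of each gene, the replicate block and all probe sets as background each gave 1, the last 4 between watered genotypes. Above-median brightness gave 0 between stressed genotypes, and the covariate 0 in WT and for the difference. Removing the Calvin cycle and aquaporin lists changed no count.

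Without 1 array, WT stress ranged from 748 (without stressed replicate 2) to 1142 and IPT stress from 54 (without watered replicate 2) to 125. The watered genotypes ranged from 966 to 1124, the stressed from 1297 to 1518 and the difference from 134 to 221. Lists ranged from 1 to 2 in WT and from 2 to 4 between stressed genotypes. The photosystem II mean in WT ranged from -0.22 to -0.19, and between stressed genotypes the light-harvesting mean ranged from 0.44 to 0.53 and the heat-shock mean from -0.74 to -0.67. The agreement r of the stress effects ranged from 0.282 to 0.406. With the replicate number as a block the counts were 1027, 110, 1304, 1587 and 165; the numbers did not pair arrays across groups (correlations -0.194 to 0.0731, 4 of 12 arrays closest to their own number). Signal over background was not analysed here.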

Other observations

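The counts of other splits for probe sets were chosen after the result was seen; those for lists were chosen before.

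Other lists, none of which camera called in any comparison, held single genes that changed. IAA3, an auxin response gene, fell in WT under stress (-0.46) and was lower in watered IPT (-0.60), 1 of 7 auxin genes each time; in WT it did not pass with the poly-A covariate (-0.49, adjusted p = 0.554). GA3ox1 rose in WT (0.63; 0.38 and adjusted p = 0.686 with that covariate), 1 of 3 gibberellin and brassinosteroid genes, and GA20OX1 was the 1 that differed between genotypes. Of 3 proline and polyamine genes, the arginine decarboxylase genes ADC (-0.54) and adc1 (-0.68) were lower in stressed IPT and ADC in watered IPT (-0.55). With the poly-A covariate neither passed in stressed IPT (-0.50 and -0.44, adjusted p = 0.0794 and 0.0923). Another adc1 probe set was lower in watered (-0.86) and in stressed IPT (-0.81), and those at -0.15 and 0.27 under stress passed in neither. The flavonoid gene DFR was higher in watered IPT (0.48; 0.34 and adjusted p = 0.0819 with that covariate), 1 of 4 phenylpropanoid genes. RPS25 rose in WT (0.61), 1 of 5 ribosomal protein genes, and was -0.02 with the poly-A covariate. Its other probe set (0.21) did not pass in WT. The chitinase CHI9 was higher in stressed IPT (0.71), 1 of 13 defence genes. The fits without 1 array lost the calls of IAA3 in WT, RPS25, ADC and DFR at least once. None of 9 flower and pollen genes, 3 ripening and seed genes, 3 genes matched for the Calvin cycle and 4 for aquaporins passed in any comparison by limma.

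Fry, which does not compare a list with other genes, called further lists that camera did not. They were gibberellin and brassinosteroid in WT stress (adjusted p = 0.0161), between watered (0.000484) and between stressed genotypes (0.00459), and ribosomal proteins in WT stress (0.0161) and between stressed genotypes (0.0357). The stress transcription factors were called in WT stress (0.0293), between watered genotypes (0.0374) and for the difference (0.0393), and oxidative stress enzymes between watered (0.000197) and stressed genotypes (1.47e-05). Photosystem II was called between watered genotypes (6.87e-06) and for the difference (0.00197). Cell wall (0.00441), sucrose and starch (0.00382) and the list matched for aquaporins (0.0336) were called between watered genotypes, and proline and polyamine (0.0228) between stressed ones.

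Each comparison of 3 against 3 arrays has 10 splits, too few for a share under 0.05, and 1 of 10 was the real one in each count of probe sets. The real counts were 1142, 137, 1396 and 1682 for WT stress, IPT stress, watered and stressed genotypes, and the highest other was 0 each time. For lists the real counts were 2, 0, 2 and 4, and the highest others 0, 1, 0 and 1; with the real 0 in IPT stress, 10 of 10 splits gave as many.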
